A study of Mus musculus with 4 samples.

How the data were processed

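Hearts of 2 wild-type (WT) and 2 Mst1/2-deficient (KO) C57BL/6 mice were measured by sequencing of polyadenylated RNA from single wells of 4 chips. Per the labels' protocols, cardiomyocytes were separated from other cells by low-speed centrifugation and libraries were made with a Nextera XT kit. The deposited values are counts per gene and well. In every well the sum over genes equalled the number of distinct gene and UMI pairs in the deposited per-well report, so the values are UMI counts and not read counts. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread 1.4.6-p1 were used with the mm10 build. The version of featureCounts, the annotation release, the strand setting and the rule for collapsing UMIs are not given in the sources used here. The deposited per-well reports also give counts of read pairs and, as text, the animal and cell fraction of each well. The planned tests assumed reads without molecular identifiers, but the same count tests fit UMI counts and were kept.

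The tables held 29245 gene columns, of which 28604 matched a gene symbol. The 70 spike-in columns took 4.98e-05% of all UMIs and were left out of library sizes and tests, and every other column named a gene. No column of per-sample values was without a sample (0 columns). Control wells (20 negative, with a median of 128.5 UMIs, and 20 positive, with a median of 174) were left out. Wells were kept with at least 10000 UMIs and 300 detected genes. This kept 1395 wells of WT replicate 1 (median 70186 UMIs and 2305 genes), 484 of WT replicate 2 (119502 and 2945.5), 649 of KO replicate 1 (144229 and 2779) and 1462 of KO replicate 2 (88919 and 2143.5). The median share of mitochondrial UMIs per well was 12.1, 33.1, 39.5 and 52.4% in the same order. Replicate numbers follow accession order and name libraries only.

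Wells were clustered with scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Counts were scaled to 10000 per well and put on a log scale, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used on all 4 libraries together. Of 17 fixed marker sets, the erythroid set was left out of naming because haemoglobin UMIs lay in nearly all NCM wells. A cluster took a class name from the other sets when at least 3 markers of the class were among its 30 leading genes, each with a log2 fold of at least 1 against other wells, and no other class had more markers among the first 10. Folds used a pseudocount of 0.5 per 10000 and were computed against other wells of the same libraries, or against all other wells where that gave no name; a name found the second way was dropped when another class had more markers within libraries. Names end in "-like" because no annotation by the authors was used. Clusters 0, 1, 5 and 9 stayed unnamed. They held haemoglobin genes (0), Cd74 (1), class II genes (5) and endothelial genes (9, with 295 wells) among their leading genes, but the rule gave them no name. Haemoglobin genes could not name cluster 0, since the erythroid set was left out. Doublets were called with Scrublet per library, which marked 20, 10, 0 and 3 wells of WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2, and were left in except in an alternative.

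UMI counts were summed over wells per library or per animal and class, and a class was tested only where every sum held at least 20 wells. Library sums were fixed in advance as the unit, with animal sums as the other unit to try. Because each library held only 1 fraction, animals are the true replicates, and the report leads with them and names genes from them. KO was compared with WT by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Adjusted p values of genes are from this test, and DESeq2 1.42.0 was run as the other tool. CPM of tested sums are scaled by TMM, while CPM of Stk4 and Stk3 per fraction are of plain totals. Gene lists, 21 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Shares of wells carry exact Clopper-Pearson intervals at 95% and two-sided exact permutation tests over animals. The animals can be parted into equal groups in 3 ways, so the smallest exact p is 0.333. A difference of genotype effects between classes was tested with edgeR on NCM sums with the animal as a block, which was chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.

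The groups, tests, marker sets, gene lists, most other settings and the rule for named genes were fixed before the data were examined. Leaving the erythroid set out of naming was a departure from this. The rule takes Stk4 and Stk3, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 10 CPM and both KO values on 1 side of both WT values, then up to 4 members of each list with the smallest p. Where fewer than 10 genes pass, the 10 genes with the smallest p and a mean of at least 10 CPM are given as values. Gene models without a name, pseudogenes and sex-linked genes were not named. Ly6a, the genes of the test between classes and the leading genes of unnamed clusters were chosen after their values were seen.

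Each fit was tested on simulated data, with counts drawn for the real genes from the real means and library sizes and 200 genes changed by a fold of 2, 4 or 8. The changed genes were drawn only from those with a mean of at least 10 CPM. The rates below thus say nothing of rarer genes, which the gene numbers beside them include. At the dispersion fitted to the animals, the test recovered 4.48, 68.7 and 95.5% of these over all wells (17891 genes), 1.49, 26.9 and 78.8% in cardiomyocyte-like wells (12353 genes), 1.49, 47.8 and 84.9% in fibroblast-like wells (14716 genes), 0, 19.4 and 57.6% in endothelial-like wells (12978 genes), 0, 19.4 and 50% in macrophage-like wells (13231 genes) and 0% at every fold in neutrophil-like wells (8794 genes). By library it recovered 0% at every fold over all wells (17663 genes), in endothelial-like wells (13304 genes) and in macrophage-like wells (12560 genes), and 0, 2.99 and 24.2% in fibroblast-like wells (14054 genes). The test between macrophage- and fibroblast-like wells recovered 0, 0 and 9.09% (14710 genes). At a dispersion of 0.01 it recovered 95.5, 98.5 and 100% in neutrophil-like wells, 71.6, 100 and 100% between classes, and 100% elsewhere. For lists, the cell cycle genes were raised 4-fold in simulated macrophage-like sums by animal at a dispersion of 0.01. Camera at both correlations and fry found this list, and camera at the preset correlation called no other. Genes were drawn independently of each other, so this run does not test false calls among correlated genes. It does not test recovery of lists at the fitted dispersion either.

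Alternatives covered the low-count filter (none, or 10 CPM in 2 sums), DESeq2 size factors and library totals in place of TMM, DESeq2's test, leaving out each library or animal, and a block on sequencing index order, which pairs chips of the same fraction. They also covered wells with at least 20000 UMIs and 1000 genes (the stricter filter), every non-control well, wells under 30% mitochondrial UMIs, wells thinned to 10000 UMIs, doublets left out, Leiden resolution 0.5 and 2.0, assignment of each well by its own highest marker score, and mitochondrial genes left out. Sums of a single fraction, haemoglobin genes left out with the mitochondrial ones, and clustering without both were added after the data were seen.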

Results

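The series asks what the kinases MST1 and MST2 do in the mouse heart, and its title places them beside the leukotriene B4 receptor in the setting of infarction. Cells of hearts from wild-type (WT) and Mst1/2-deficient (KO) C57BL/6 mice were spread over chips with 1 barcode per well, and the polyadenylated RNA of each well was sequenced. Low-speed centrifugation had separated cardiomyocytes from the remaining cells. The labels do not say whether the hearts were injured, in which cells the genes were deleted or which allele was used. The per-well reports name the animal of every well, and these names give 2 WT animals (WT1 and WT2) and 2 KO animals (KO1 and KO2). The 4 libraries are 4 chips, and each chip held a single genotype and a single cell fraction. WT replicate 1 and KO replicate 2 held the non-cardiomyocyte (NCM) fraction, and WT replicate 2 and KO replicate 1 held the cardiomyocyte (CM) fraction. Each animal was spread over both chips of its genotype, so the animal is the replicate below. Within a fraction, genotype and chip are the same split and their effects cannot be told apart.

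The values were UMI counts, the number of distinct tagged molecules per gene and well. The WT NCM chip kept 1395 of 1623 wells with a median of 70186 UMIs, and the KO NCM chip 1462 of 1497 wells with a median of 88919. The WT CM chip kept 484 of 501 wells at a median of 119502 UMIs and the KO CM chip 649 of 654 wells at 144229. The kept wells held 202631859 and 175453852 UMIs on the NCM chips of WT and KO, and 78308792 and 116884766 on the CM chips. Per animal, the NCM wells gave 92741821 (WT1), 109890038 (WT2), 70696300 (KO1) and 104757552 UMIs (KO2). The CM wells gave 31387274, 46921518, 24921656 and 91963110 in the same order. Negative control wells held a median of 128.5 UMIs. Binomial intervals and count floors given below cover counting error only. With 2 animals per genotype, a two-sided exact permutation test cannot go below p = 0.333.

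Stk4 encodes MST1 and Stk3 encodes MST2. Stk4 (ENSMUSG00000018209) lies on chromosome 2 of mm10 from 164070322 to 164155524 on the plus strand, and Stk3 (ENSMUSG00000022329) on chromosome 15 from 34875496 to 35178921 on the minus strand. In NCM wells, Stk4 stood at 48.5 and 40.4 CPM (counts scaled to a common library total) in WT1 and WT2 and at 17.1 and 19.3 CPM in KO1 and KO2. In CM wells it stood at 19.98 and 9.12 CPM against 9.43 and 5.89 CPM. Stk3 was 21.4 and 32.9 CPM in WT against 10.8 and 13.6 CPM in KO in NCM wells, and 7.84 and 8.87 against 16.4 and 7.54 CPM in CM wells. The NCM wells of KO animals also held more mitochondrial and haemoglobin RNA. In CPM of the UMIs that were neither, Stk4 in NCM wells was 53.1 and 47.3 in WT against 45.8 and 37.5 in KO, and Stk3 was 23.5 and 38.6 against 29.0 and 26.3. With both fractions summed per animal, Stk4 differed by log2 −0.66 (SE 0.291, edgeR adjusted p = 0.526) and Stk3 by −0.25 (SE 0.354, edgeR adjusted p = 0.848), and neither passed. The sign of Stk3 turned in wells under 30% mitochondrial UMIs (0.12), in CM wells alone (0.50) and without WT2 (0.12). By class, Stk4 differed by log2 −0.96 (SE 0.568, edgeR adjusted p = 0.692) in macrophage-like, −0.21 (SE 0.441) in fibroblast-like, −0.25 (SE 0.980) in endothelial-like, 0.68 (SE 0.846) in cardiomyocyte-like and 1.57 (SE 1.20) in neutrophil-like wells. Leaving out each animal, Stk4 ranged from −2.315 to 0.56 in endothelial-like and from −0.32 to 1.25 in cardiomyocyte-like wells, so its sign turned in both. In the CM cardiomyocyte-like wells it was 8.77 and 7.59 in WT against 24.7 and 6.43 in KO, in CPM of the UMIs that were neither mitochondrial nor haemoglobin. The value of KO1 rested on 105 UMIs in 7 of 137 wells. Stk4 UMIs lay in 10 of 113 and 24 of 180 such wells of WT and in 29 of 246 of KO2. The share of wells with Stk4 was thus not higher in KO1. The labels do not give the deleted part of either gene, so UMIs in KO wells cannot check the deletion.

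**Figure D1:**
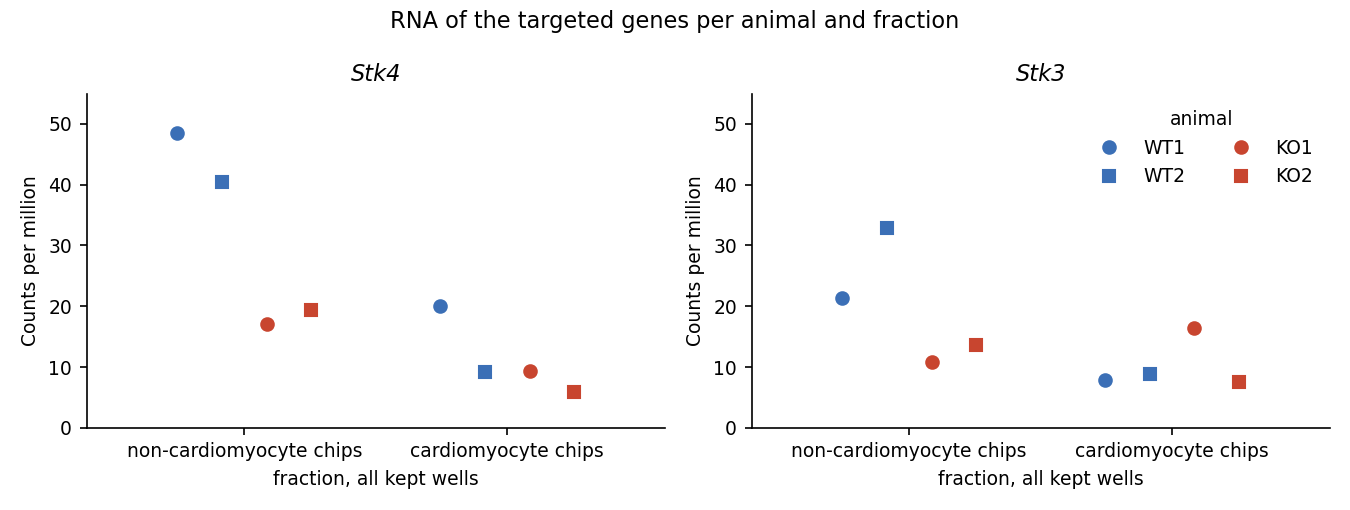
Expression in CPM of Stk4 and Stk3 over the kept wells of each animal, 1 point per animal, for the non-cardiomyocyte (NCM) and cardiomyocyte (CM) chips. In NCM wells Stk4 lay at 48.5 and 40.4 CPM in WT against 17.1 and 19.3 CPM in KO, whereas Stk3 in CM wells of KO1 (16.4 CPM) lay above both WT animals.

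The RNA of the KO NCM wells had another make-up than that of the WT NCM wells. Mitochondrially encoded transcripts took 7.45 and 11.2% of NCM UMIs in WT1 and WT2 and 58.1 and 36.5% in KO1 and KO2. Haemoglobin transcripts took 1.19 and 3.42% against 4.48 and 11.96%, and on the CM chips 0.00188 and 0.00220% against 0.1005 and 0.263%. Every class with enough NCM wells had the larger mitochondrial share in both KO animals. In fibroblast-like NCM wells the mitochondrial share was 4.79 and 6.66% in WT against 42.3 and 27.5% in KO, in endothelial-like wells 8.58 and 11.5% against 51.0 and 39.7%, in macrophage-like wells 4.08 and 5.52% against 43.3 and 24.7%, and in neutrophil-like wells 10.9 and 12.02% against 62.4 and 42.4%. On the CM chips the mitochondrial shares of the same classes overlapped between genotypes or lay closer. Fibroblast-like CM wells had 21.9 and 25.2% in WT against 19.8 and 24.4% in KO, and macrophage-like CM wells 27.5 and 20.8% against 32.3 and 28.1%. Cardiomyocyte-like wells had 48.3 and 42.1% in WT against 61.2 and 38.4% in KO. All genotype comparisons of genes below stand beside these shares.

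**Figure D2:**
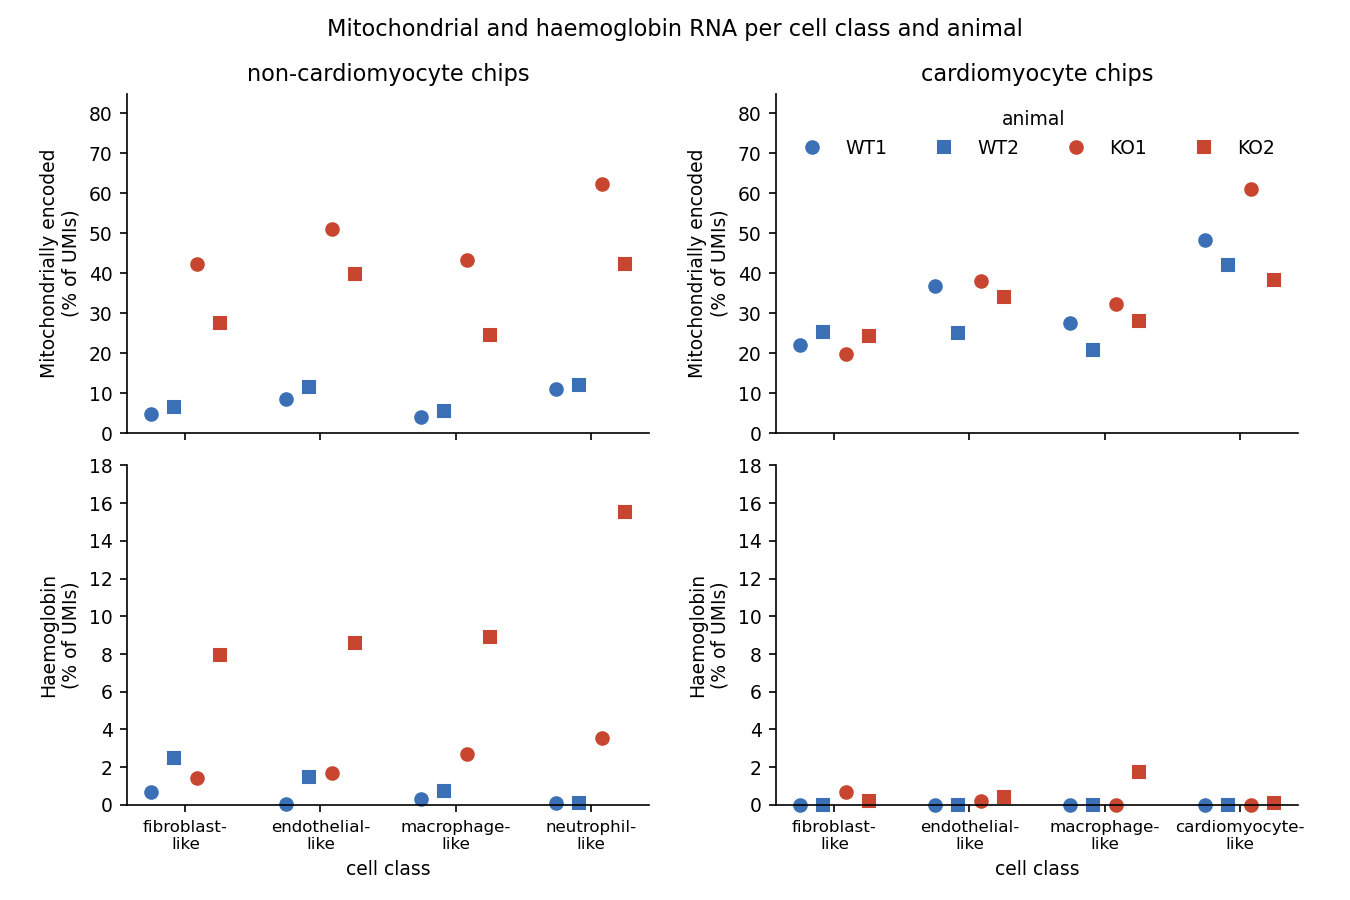
Percent of UMIs on mitochondrially encoded genes (upper panels) and haemoglobin genes (lower panels) in each class of wells, 1 point per animal, on the non-cardiomyocyte (left) and cardiomyocyte (right) chips. In NCM macrophage-like wells the mitochondrial share was 4.08 and 5.52% in WT and 43.3 and 24.7% in KO, while on the CM chips it was 27.5 and 20.8% against 32.3 and 28.1%.

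Over all wells summed per animal, genes of fetal and atrial muscle had more transcripts in KO hearts. Sln, the sarcolipin that restrains the calcium pump of atrial muscle, stood at 29.7 and 40.1 CPM in WT and at 405 and 415 CPM in KO (log2 3.55, SE 0.285, edgeR adjusted p = 0.233). Myl4, the atrial essential light chain, stood at 11.3 and 12.3 against 76.4 and 140.5 CPM (log2 3.20, SE 0.373, edgeR adjusted p = 0.323). Nppa, which encodes atrial natriuretic peptide, differed by log2 2.69 (SE 0.372), and Xirp2, an actin-binding protein of stressed muscle, by 2.39 (SE 0.335), both at an edgeR adjusted p of 0.390. The 14 measured fetal and hypertrophy genes rose as a list (median log2 1.63, camera adjusted p = 4.42e-14; adjusted p = 0.512 with an estimated correlation). Of these, 9 were higher adjusted over the list alone and 0 over all genes. The mitochondrially encoded list also rose (median 2.12, camera adjusted p = 6.98e-17; adjusted p = 0.512 with an estimated correlation), with 12 of 13 genes higher adjusted over the list alone and 0 over all genes. The median of this list was −0.05 on the CM chips alone (camera adjusted p = 0.757).

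Genes of antigen presentation and inflammation had fewer transcripts in KO hearts. H2-Aa, a chain of the MHC class II complex that presents peptides to T cells, stood at 964 and 995 CPM in WT and at 227 and 117 CPM in KO (log2 −2.51, SE 0.382, edgeR adjusted p = 0.427). H2-Ab1 differed by log2 −2.17 (SE 0.277) over both fractions, yet by 0.58 on the CM chips alone. The 8 class II genes fell as a list (median −1.87, camera adjusted p = 2.43e-10; adjusted p = 0.512 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. Their median was −0.05 on the CM chips alone (camera adjusted p = 0.102). Of 28 inflammatory cytokines and chemokines, 22 were lower in KO and 7 were lower adjusted over the list alone, with 0 over all genes. This list fell too (median −0.79, camera adjusted p = 1.82e-09; adjusted p = 0.512 with an estimated correlation). The macrophage attractants Ccl4 and Ccl3 differed by log2 −1.50 (SE 0.284) and −1.52 (SE 0.332). The leukotriene and prostanoid genes fell by camera as well (median −0.37, adjusted p = 8.13e-04; adjusted p = 0.512 with an estimated correlation), and 17 of 21 were lower. Dpep1, which converts leukotriene D4 to E4, was 91.7 and 115 CPM in WT against 39.6 and 33.6 in KO (log2 −1.50, SE 0.259) and was the 1 member lower adjusted over the list alone, with 0 over all genes. Alox5ap, the partner of 5-lipoxygenase, was 298 and 265 against 142 and 138 CPM (log2 −1.01, SE 0.232). The neutrophil genes Retnlg (log2 −3.00, SE 0.340) and Il1f9 (log2 −4.08, SE 0.520) were also lower. Macrophage- and neutrophil-like wells were a smaller part of the KO NCM wells too, so these sums do not show a fall per cell. T or NK cell-like NCM wells were not, at 1.16 and 1.28% in WT against 2.10 and 1.34% in KO. Macrophage markers took 0.847 and 0.972% of other UMIs over the NCM wells of WT against 0.413 and 0.5004% in KO, and the shares of macrophage- and neutrophil-like wells given below were lower. Of the unnamed clusters, cluster 5, led by class II genes, held 34 and 22 NCM wells in WT against 19 and 6 in KO, and cluster 1, with Cd74 among its leading genes, 140 and 92 against 23 and 29. In the NCM wells of cluster 5 H2-Aa stood at 17231 and 20495 in WT and at 3817 and 4506 in KO, in CPM of the UMIs that were neither mitochondrial nor haemoglobin. In those of cluster 1 it overlapped, at 1512 and 1835 in WT against 1828 and 1070 in KO. None of these genes passed over all genes.

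Most lists of muscle work and energy supply depended on KO2, whose sum held the largest part of UMIs from the CM chip (91963110 beside 104757552 from the NCM chip, given above for each animal). Over all wells, glycolysis (median log2 0.63, camera adjusted p = 1.55e-04), sarcomere (0.87, 3.14e-04), calcium handling (0.58, 0.00359), fatty acid oxidation (0.44, 0.0108) and nuclear respiratory chain genes (0.44, 0.0226) rose. Their adjusted p was 0.637, 0.637, 0.637, 0.737 and 0.828 with an estimated correlation. Without KO2 the medians were −0.39 for sarcomere, −0.46 for calcium handling, −0.67 for fatty acid oxidation and −0.65 for respiratory chain genes. On the CM chips alone they were −0.14, −0.57, −0.35 and −0.24, and on the NCM chips alone the respiratory chain stood at −0.11. Angiogenesis genes also rose (0.82, camera adjusted p = 4.28e-04; adjusted p = 0.637 with an estimated correlation). Interferon-stimulated genes (0.29, camera adjusted p = 0.0212), the Hippo pathway core (0.38, 0.0226) and tissue-repair macrophage genes (−0.54, 0.0468) were called, each with an adjusted p of 0.588 to 0.637 with an estimated correlation. Without KO2 the interferon median turned to −0.14, and with library totals in place of TMM the interferon, Hippo and respiratory chain medians were −0.39, −0.29 and −0.18. The members of these lists past the test adjusted over the list alone were Des, Sln, Cmpk2 and Rsad2, and over all genes there were 0. The lists of YAP/TAZ targets (median 0.09, camera adjusted p = 0.151), extracellular matrix (−0.01, 0.137), antioxidant (−0.05, 0.148), immediate early (−0.04, 0.790), apoptosis (−0.11, 0.393), cell cycle (0.08, 0.790) and efferocytosis genes (0.05, 0.957) did not pass. For extracellular matrix and immediate early genes the median had the opposite sign to the mean and, for the former, to the test.

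Over all wells edgeR called 0 of 17891 genes by animal, 1751 had an unadjusted p under 0.05, and DESeq2 called 212 higher and 266 lower. Changes are relative to the typical gene, since library totals alone moved the median log2 difference of all genes from 0.01 to −0.67 over all wells. That shift reached −0.36 in fibroblast-like, −0.52 in endothelial-like, −0.40 in macrophage-like and −0.76 in neutrophil-like wells, while cardiomyocyte-like wells stayed at 0.01. With libraries in place of animals as the unit, edgeR called 0 of 17663 genes, with 236 at an unadjusted p under 0.05 and 6 higher and 15 lower by DESeq2. Camera called 9 lists by library, all of them lost with an estimated correlation (adjusted p = 0.963 for each). Within classes the library sums gave 0 genes by edgeR for fibroblast-like (335 at an unadjusted p under 0.05; DESeq2 11 higher, 12 lower), endothelial-like (249; 10 and 9) and macrophage-like wells (383; 26 and 19).

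In macrophage-like wells the class II genes stood lower in KO. H2-Aa was 1418 and 2059 CPM in WT against 200.2 and 155 CPM in KO (log2 −3.29, SE 0.339, edgeR adjusted p = 0.493). H2-Eb1 was 544 and 906 against 176 and 89.2 CPM (log2 −2.45, SE 0.454, edgeR adjusted p = 0.498), and Cd74, the invariant chain that escorts class II proteins, 54.6 and 97.7 against 25.2 and 14.9 CPM (log2 −1.93, SE 0.545). The class II list fell (median −2.06, camera adjusted p = 1.07e-07; adjusted p = 0.363 with an estimated correlation), with 5 of 8 genes lower adjusted over the list alone and 0 over all genes. Its median was 0.20 on the CM chips alone (camera adjusted p = 0.673), with H2-Eb1 at 0.47. Inflammatory genes fell (median −0.46, camera adjusted p = 3.19e-05; adjusted p = 0.217 with an estimated correlation), with 22 of 27 lower and 0 past the test over the list alone or over all genes. Osm (log2 −1.65, SE 0.496), Il1b (−0.81, SE 0.272) and Il6 (−1.55, SE 0.524), all secreted cytokines, were among the lower members. That median was −0.01 on the CM chips alone (camera adjusted p = 0.558), with Il1b at 0.31. The leukotriene and prostanoid list fell (median −0.65, camera adjusted p = 0.0247; adjusted p = 0.417 with an estimated correlation), 0 genes passed over the list alone or over all genes, and 2 were lower at an unadjusted p under 0.05. Ltc4s, the leukotriene C4 synthase, stood at 96.6 and 263 CPM in WT and 26.4 and 74.6 in KO (log2 −1.83, SE 0.674). On either fraction alone this call was lost (adjusted p = 0.0629 on NCM and 0.356 on CM chips).

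Over both fractions summed, several muscle, matrix and endothelial transcripts were higher in the macrophage-like wells of KO hearts. Xirp2 was 32.9 and 42.3 CPM in WT against 317 and 194 CPM in KO (log2 2.76, SE 0.411, edgeR adjusted p = 0.498), and Nppa differed by log2 2.94 (SE 0.514). Of 13 fetal and hypertrophy genes 11 were higher adjusted over the list alone and 0 over all genes (median 1.80, camera adjusted p = 1.78e-12; adjusted p = 0.217 with an estimated correlation). The basement membrane gene Col4a1 was 43.9 and 27.0 against 143 and 531 CPM (log2 3.25, SE 0.676), and the extracellular matrix list rose (median 1.13, camera adjusted p = 8.19e-09; adjusted p = 0.217 with an estimated correlation), with 3 of 32 genes higher over the list alone and 0 over all genes. Kdr and Cdh5, a receptor and an adhesion protein of endothelial cells, differed by log2 2.69 (SE 0.519) and 2.60 (SE 0.549). The angiogenesis list rose (median 1.4, camera adjusted p = 2.80e-05; adjusted p = 0.217 with an estimated correlation), with 4 of 26 genes higher over the list alone and 0 over all genes. Endothelial markers took 0.0370 and 0.0488% of other UMIs in the NCM macrophage-like wells of WT and 0.349 and 0.162% in KO. Cardiomyocyte markers took 0.0818 and 0.171% against 0.261 and 0.482%, fibroblast markers 0.139 and 0.139% against 0.216 and 0.390%, and macrophage markers 2.57 and 2.85% against 1.46 and 1.36%. The CM macrophage-like wells did not follow, with endothelial markers at 0.0591 and 0.0384% against 0.0438 and 0.0426% and cardiomyocyte markers at 3.84 and 4.94% against 1.39 and 5.44%. These CM wells gave 7209580 UMIs beside 20171449 from the NCM chip in WT1 and 4202516 beside 28095301 in WT2, against 3588682 beside 5024326 in KO1 and 5234346 beside 13329120 in KO2, so they were a larger part of the KO sums. The matrix and angiogenesis medians were 0.08 and 0.26 on the CM chips alone, and neither list was called there (adjusted p = 0.969 and 0.727).

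The mitochondrially encoded genes also rose in macrophage-like wells (median 2.22, camera adjusted p = 1.11e-25; adjusted p = 0.330 with an estimated correlation), with 11 of 12 higher over the list alone and 0 over all genes, but on the CM chips alone the median was 0.29 (adjusted p = 0.110). Sarcomere (0.73, 1.85e-08), fatty acid oxidation (0.57, 0.00196), YAP/TAZ target (0.49, 0.0161), respiratory chain (0.25, 0.0316) and glycolysis genes (0.27, 0.0490) were called upward by camera, and each call was lost with an estimated correlation (adjusted p = 0.455, 0.540, 0.339, 0.735 and 0.606). Des, the desmin filament of muscle, was the only member of these higher adjusted over its list alone, and 0 passed over all genes. On the CM chips alone the sarcomere, fatty acid and respiratory chain medians turned to −0.27, −0.30 and −0.38. Without KO2 the fatty acid, respiratory chain and glycolysis medians were −0.33, −0.40 and −0.01, and library totals alone turned the respiratory chain to −0.14. Over all genes edgeR called 0 of 13231, with 1146 at an unadjusted p under 0.05 and 242 higher and 122 lower by DESeq2.

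In fibroblast-like wells, lists of matrix, tissue-repair and vessel genes were called upward in KO by camera at the preset correlation only. The inducible chaperones Hspa1b and Hspa1a differed by log2 2.44 (SE 0.304) and 2.62 (SE 0.333), both at an edgeR adjusted p of 0.317. They were the 2 of 28 immediate early and stress genes higher adjusted over the list alone, with 0 over all genes (median 0.25, camera adjusted p = 0.00195; adjusted p = 0.531 with an estimated correlation), and with library totals alone the median of that list was −0.09. Comp, a matrix protein that binds collagen, was 1.92 and 1.91 CPM in WT against 17.3 and 30.1 CPM in KO (log2 3.63, SE 0.637, edgeR adjusted p = 0.402), and Loxl2, which crosslinks collagen, differed by log2 1.04. The extracellular matrix list rose (median 0.41, camera adjusted p = 3.20e-05; adjusted p = 0.437 with an estimated correlation), with 25 of 34 genes higher, Comp alone past the list's own adjustment and 0 over all genes. Among tissue-repair genes (median 0.72, camera adjusted p = 6.45e-05; adjusted p = 0.437 with an estimated correlation), Arg1, which breaks down arginine, and Spp1, which encodes osteopontin, were the 2 of 20 higher adjusted over the list alone, with 0 over all genes. They differed by log2 2.26 (SE 0.427) and 0.97 (SE 0.206). Immune transcripts were higher in the same NCM wells: class II genes took 0.0688 and 0.0552% of other UMIs in WT against 0.128 and 0.107% in KO, and macrophage markers 0.116 and 0.0819% against 0.118 and 0.193%. Alox5ap stood at 44.7 and 39.6 against 104 and 173, in CPM of these UMIs. In the fewer CM fibroblast-like wells they went the other way, with class II genes at 0.0307 and 0.0738% against 0.00650 and 0.00842%, macrophage markers at 0.112 and 0.0867% against 0.0160 and 0.0295%, and Alox5ap at 26.8 and 39.5 against 0 and 10.8. Efferocytosis genes (0.77, 2.00e-04) and interferon-stimulated genes (0.71, 3.16e-04) were called upward with 0 genes past the test over the list alone or over all genes, and had adjusted p = 0.432 and 0.531 with an estimated correlation. The interferon median was 0.03 without KO2, where the test pointed downward (adjusted p = 0.877).

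Over both fractions summed, several endothelial and muscle transcripts were higher in KO fibroblast-like wells too. Cdh5 was 5.94 and 9.11 CPM in WT against 52.4 and 52.3 CPM in KO (log2 2.80, SE 0.438, edgeR adjusted p = 0.362), and Myl7, the atrial regulatory light chain, 8.88 and 10.3 against 50.8 and 57.9 CPM (log2 2.5, SE 0.391, edgeR adjusted p = 0.362). The angiogenesis (median 1.02, camera adjusted p = 7.46e-07) and fetal lists (1.04, 2.98e-05) rose, both with adjusted p = 0.432 with an estimated correlation. Adjusted over the list alone 2 of 26 and 3 of 14 genes were higher, and over all genes 0. In NCM fibroblast-like wells, endothelial markers took 0.102 and 0.0864% of other UMIs in WT against 0.261 and 0.168% in KO, while cardiomyocyte markers overlapped, at 0.0830 and 0.175% against 0.139 and 0.378%. In CM fibroblast-like wells both overlapped, with endothelial markers at 0.0285 and 0.0990% against 0.107 and 0.0586% and cardiomyocyte markers at 3.72 and 3.95% against 0.895 and 4.33%. Of 13 mitochondrially encoded genes 12 were higher over the list alone and 0 over all genes (median 2.47, camera adjusted p = 1.95e-23; adjusted p = 0.437 with an estimated correlation). Glycolysis genes were called upward (0.30, camera adjusted p = 0.00195; adjusted p = 0.437 with an estimated correlation) with 0 genes over the list alone or over all genes, but their median was −0.06 with library totals alone. Over all genes edgeR called 0 of 14716, with 1444 at an unadjusted p under 0.05 and 236 higher and 116 lower by DESeq2.

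In endothelial-like wells, cell cycle genes stood lower in KO over the summed class, which joined clusters 3 and 4. Ube2c, which marks mitotic proteins for destruction, was 96.4 and 53.2 CPM in WT against 20.1 and 25.8 CPM in KO (log2 −1.70, SE 0.522, edgeR adjusted p = 0.863), and Bub1, a spindle checkpoint kinase, differed by log2 −2.46. The 25 cell cycle genes fell as a list (median −0.78, camera adjusted p = 0.00339; adjusted p = 0.839 with an estimated correlation), with 19 lower, 6 of them at an unadjusted p under 0.05, and 0 past the test over the list alone or over all genes. With every well thinned to 10000 UMIs the list's median was −0.06 and its test pointed upward (adjusted p = 0.834). Cluster 3, with the histone gene Hist1h2ap among its leading genes, held 9 of 66 and 18 of 137 NCM wells of the class in WT against 6 of 67 and 6 of 116 in KO. In NCM wells the list took 1.13 and 0.4201% of other UMIs in WT against 0.557 and 0.494% in KO in cluster 3, and 0.171 and 0.129% against 0.141 and 0.173% in cluster 4, which overlap. Most wells of cluster 3 lay on the CM chips, where the list took 0.233 and 0.0928% in WT against 0.198 and 0.0786% in KO, which overlap too. These values were added after the data were seen, and a change of cluster mix was not separated from a change in the cells. Tmem204, an endothelial membrane protein, was 214 and 240.1 against 62.7 and 58.6 CPM (log2 −1.90, SE 0.363), and Vegfc, a growth factor of lymphatic vessels, differed by log2 −2.19 (SE 0.714). Angiogenesis genes fell slightly (median −0.17, camera adjusted p = 0.0471; adjusted p = 0.839 with an estimated correlation), with 0 genes over the list alone or over all genes, and were not called on either fraction alone. The markers of the class fell with them on the NCM chips, from 1.58 and 2.09% of other UMIs in WT to 1.27 and 1.09% in KO, and overlapped on the CM chips, at 0.663 and 0.465% against 0.753 and 0.376%. Fetal genes rose (median 1.58, camera adjusted p = 7.66e-09; adjusted p = 0.839 with an estimated correlation), with 6 of 14 higher over the list alone and 0 over all genes. Xirp2 was 53.7 and 45.6 CPM in WT and 320.4 and 377 in KO (log2 2.81, SE 0.368). In the CM endothelial-like wells cardiomyocyte markers took 4.69 and 7.68% of other UMIs in WT and 2.21 and 7.18% in KO, and in NCM wells 0.172 and 0.287% against 0.175 and 0.628%.

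Among endothelial-like wells, 11 of 12 mitochondrially encoded genes were higher over the list alone and 0 over all genes (median 1.89, camera adjusted p = 2.18e-28; adjusted p = 0.839 with an estimated correlation), while on the CM chips alone the median was −0.05. Sarcomere (1.03, 3.88e-04), glycolysis (0.76, 1.11e-04), respiratory chain (0.58, 0.0112), extracellular matrix (0.31, 0.00148) and interferon-stimulated genes (0.35, 0.0219) were called upward, with adjusted p of 0.839 to 0.845 with an estimated correlation and 0 genes over the list alone or over all genes. Without KO2 the sarcomere and respiratory chain medians turned to −0.77 and −0.74, on the CM chips alone to −0.48 and −0.42, and with library totals alone the matrix median was −0.24. The CM chip gave a larger part of KO2's endothelial-like sum than of the others, with 17312381 UMIs beside 12364765 from the NCM chip, against 3804436 beside 6451601 in WT1, 4713611 beside 15262534 in WT2 and 3252446 beside 6868617 in KO1. Over all genes edgeR called 0 of 12978, with 729 at an unadjusted p under 0.05 and 57 higher and 52 lower by DESeq2.

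In cardiomyocyte-like wells, genes of fetal and atrial muscle stood higher in KO and genes of oxidative metabolism lower. Nes, the filament protein nestin, was 5.82 and 2.66 CPM in WT against 36.8 and 14.7 CPM in KO (log2 2.61, SE 0.719, edgeR adjusted p = 0.915). Mybphl, an atrial myosin-binding protein, was 1.33 and 1.62 against 54.9 and 17.6 CPM (log2 4.61, SE 0.741, edgeR adjusted p = 0.915), and Myl9, a smooth muscle light chain, differed by log2 3.22 (SE 0.581). Fetal genes rose as a list (median 1.34, camera adjusted p = 4.64e-16; adjusted p = 0.843 with an estimated correlation), with 9 of 13 higher over the list alone and 0 over all genes. Respiratory chain genes fell (median −0.39, camera adjusted p = 1.40e-09; adjusted p = 0.893 with an estimated correlation), with 48 of 50 lower and 0 past the test over the list alone or over all genes, and the median was 0.05 without KO1. Uqcrh, a complex III subunit, was 1945 and 2061 CPM in WT against 671 and 1664 CPM in KO. Fatty acid oxidation genes fell (median −0.58, camera adjusted p = 1.31e-05; adjusted p = 0.893 with an estimated correlation), with 25 of 30 lower and 0 over the list alone or over all genes, among them Acadm, a medium-chain dehydrogenase (log2 −0.78, SE 0.458). Calcium handling genes fell (median −0.65, camera adjusted p = 0.00923) and so did sarcomere genes (−0.27, 0.0399), both with adjusted p = 0.893 with an estimated correlation. Camk2d, a calcium-dependent kinase, was 64.9 and 78.7 against 20.6 and 37.8 CPM (log2 −1.29, SE 0.440). Sln went the other way and was the 1 calcium gene past the list's own adjustment, with 0 over all genes. Interferon-stimulated genes rose (median 1.09, camera adjusted p = 4.35e-04; adjusted p = 0.843 with an estimated correlation), with 22 of 25 higher and 0 over the list alone or over all genes, and Xaf1 differed by log2 2.00 (SE 0.607).

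The class joined 2 clusters in different parts. Cluster 14, led by Sln, Myl7 and Myl4, held 20 of 113 and 66 of 180 CM cardiomyocyte-like wells in WT against 6 of 137 and 45 of 246 in KO, and cluster 10 held the others. The atrial light chain Myl7 was 388 and 512, in CPM of the UMIs that were neither mitochondrial nor haemoglobin, in the CM cardiomyocyte-like wells of WT and 3570.3 and 1478 in KO, and the ventricular light chain Myl2 8939 and 11636 against 3675 and 7652. Sln was 264 and 384 against 6246 and 1434 on the same scale. In cluster 10 alone, Myl7 was 447 and 324 in WT against 1133 and 863 in KO and Sln 327 and 105 against 1104 and 734. In cluster 14 Myl7 was 179 and 756 against 13158 and 4292, where KO1 had only 6 wells. These values per cluster were added after the data were seen and not tested. Cardiomyocyte markers took 9.64 and 10.7% of these UMIs in WT and 6.38 and 9.43% in KO. KO1 lay farther from WT than KO2 in each of these values, and without KO2 edgeR called 651 genes, against 8 to 23 without each of the other animals. With all 4 animals edgeR called 0 of 12353 genes, 661 had an unadjusted p under 0.05, and DESeq2 called 80 higher and 30 lower.

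**Figure D3:**
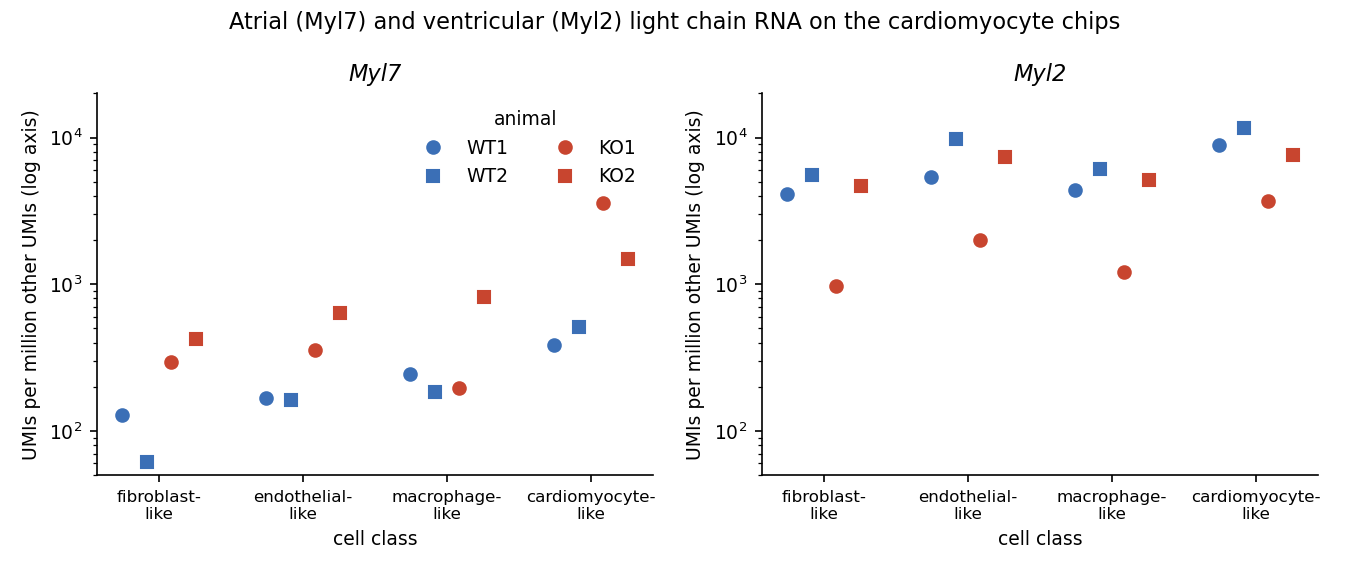
Myl7 (atrial) and Myl2 (ventricular), in CPM of the UMIs that were neither mitochondrial nor haemoglobin, on a log axis, by class on the cardiomyocyte chips, 1 point per animal. In cardiomyocyte-like wells Myl7 lay at 388 and 512 in WT against 3570.3 and 1478 in KO, and Myl2 at 8939 and 11636 against 3675 and 7652.

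Neutrophil-like wells gave the only genes past the test, 6 genes higher in KO. They were the haemoglobin genes Hbb-bt (33.2 and 19.4 CPM in WT against 3487 and 6099 CPM in KO), Hbb-bs (114 and 59.8 against 11269 and 19541), Hba-a1 (487 and 510.1 against 21606 and 53994) and Hba-a2 (182 and 268 against 11067 and 23786), and the mitochondrially encoded mt-Cytb and mt-Nd1. Hbb-bt rose by log2 7.51 (SE 0.659, edgeR adjusted p = 0.00656), mt-Cytb by 2.78 (SE 0.333, edgeR adjusted p = 0.0405) and mt-Nd1 by 2.78 (SE 0.345, edgeR adjusted p = 0.0435). Leaving out WT1 or WT2 gave 0 genes, and leaving out KO1 or KO2 gave 21 and 18. Clustering without mitochondrial and haemoglobin genes also gave 0 genes. Neutrophils do not make haemoglobin, and haemoglobin took 0.115 and 0.108% of UMIs in the NCM neutrophil-like wells of WT and 3.55 and 15.5% in KO. Neutrophil markers took 2.60 and 2.29% of other UMIs in WT against 1.03 and 1.10% in KO. Of 12 mitochondrially encoded genes 11 were higher over the list alone and 2 over all genes (median 2.80, camera adjusted p = 5.68e-34; adjusted p = 0.524 with an estimated correlation). edgeR tested 8794 genes, of which 701 had an unadjusted p under 0.05, and DESeq2 called 146 higher and 140 lower.

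Inflammatory genes fell in neutrophil-like wells (median −1.38, camera adjusted p = 1.16e-08; adjusted p = 0.524 with an estimated correlation), with 22 of 25 lower, 4 of them over the list alone and 0 over all genes. Cxcl1, which attracts neutrophils, was 991 and 4289 CPM in WT against 497 and 434 CPM in KO (log2 −2.50, SE 0.702, edgeR adjusted p = 0.558), and Nlrp3, the inflammasome sensor, 219 and 369 against 58.6 and 90.4 CPM. Antioxidant genes fell (median −1.02, camera adjusted p = 0.0148) and so did class II genes (−1.61, 0.00318), with adjusted p = 0.574 and 0.524 with an estimated correlation. Prdx6, a peroxidase, was 598 and 596 CPM against 106 and 50.3 CPM (log2 −2.94, SE 0.668) and the 1 antioxidant gene past its list's own adjustment, while class II genes had 0, and neither list had any over all genes. Asprv1, a protease found in neutrophils, was 272 and 362 against 6.82 and 5.39 CPM (log2 −5.69, SE 0.841, edgeR adjusted p = 0.0957). Fetal (median 2.75, camera adjusted p = 4.96e-10), angiogenesis (1.21, 0.00318), interferon-stimulated (0.70, 0.00494), fatty acid oxidation (1.05, 0.00176) and Hippo genes (1.47, 0.0113) rose, with adjusted p of 0.524 to 0.574 with an estimated correlation. Adjusted over the list alone, 9 of 12 fetal genes were higher and none of the others, and over all genes 0. Sarcomere (2.01, 3.34e-06), calcium handling (1.83, 0.0420) and respiratory chain genes (1.13, 1.27e-06) were called upward, each with adjusted p = 0.574 with an estimated correlation, and 4, 0 and 0 genes passed over the list alone and 0 over all genes. Without KO2 these medians turned to −0.70, −0.29 and −0.57. Of KO2's neutrophil-like wells 18, with 2222596 UMIs, came from the NCM and 8, with 1733344 UMIs, from the CM chip, while the CM wells of WT1, WT2 and KO1 gave 417691, 165602 and 189501 UMIs beside 6112456, 3529447 and 3922817. Cardiomyocyte markers took 8.26% of other UMIs in KO2's CM neutrophil-like wells and 0.745% in its NCM ones.

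Macrophage-like wells were a smaller part of the KO NCM fraction, at 14.6 ± 1.18% of wells in WT and 6.97 ± 0.558% in KO (SD, n = 2 animals each; exact permutation p = 0.333). Per animal the shares were 15.5% (exact Clopper-Pearson 95% interval 12.8 to 18.4) and 13.8% (11.3 to 16.6) in WT, and 6.57% (4.87 to 8.65) and 7.36% (5.59 to 9.48) in KO. Fibroblast-like wells made up 20.5 ± 2.66% against 16.0 ± 3.18% and neutrophil-like wells 8.05 ± 3.74% against 3.65 ± 1.76% (SD, n = 2 each; exact permutation p = 0.333 for both). Endothelial-like wells made up 14.5 ± 7.04% against 12.4 ± 4.35% (exact permutation p = 0.667), and the sign of this difference depended on the processing, since clustering without mitochondrial and haemoglobin genes gave 12.8 points more in KO. In the CM fraction cardiomyocyte-like wells made up 59.8 ± 8.40% in WT and 57.9 ± 8.49% in KO (exact permutation p = 0.667). That difference of −1.86 points became −15.3 points at Leiden resolution 2.0. No share can pass the exact permutation test with 2 animals per genotype. Unnamed clusters held 33.1% of NCM wells in WT and 54.96% in KO, which lowers the shares of named classes in KO. One of them, cluster 9, was led by endothelial genes (Gpihbp1, Flt1, Rgcc, Rbp7 and Fabp4) and held 198 and 47 NCM wells of KO1 and KO2 against 2 and 28 of WT1 and WT2. Endothelial markers took 1.34 and 0.922% of other UMIs there in KO, beside 1.27 and 1.09% in the endothelial-like NCM wells of KO. These wells are in neither the endothelial-like share nor its gene comparison.

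**Figure D4:**
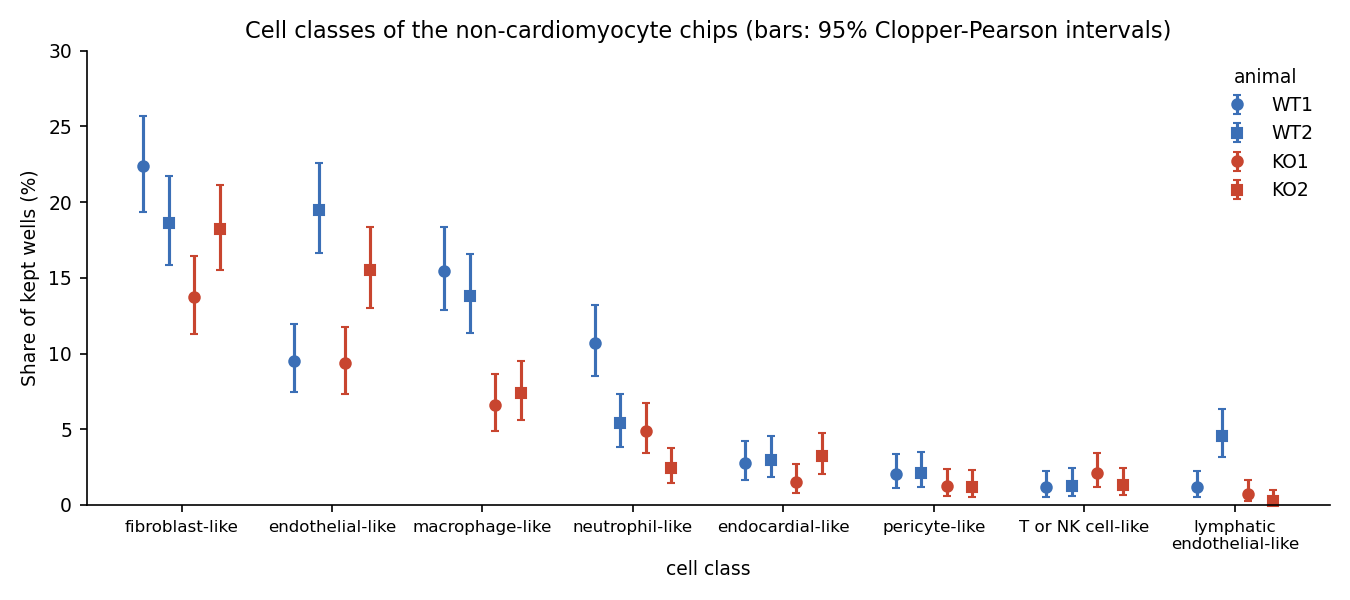
Percent of kept non-cardiomyocyte wells in each class, 1 point per animal with its exact Clopper-Pearson 95% interval. Macrophage-like wells were 15.5 and 13.8% in WT against 6.57 and 7.36% in KO, while endothelial-like wells overlapped between genotypes.

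Whether the difference between WT and KO wells varied by class was tested directly on the NCM chips, where genotype and chip are the same split. The fit over macrophage-, fibroblast- and endothelial-like wells was chosen after the data were seen. H2-Aa and H2-Eb1 fell in macrophage-like wells relative to fibroblast-like wells. H2-Aa was 2107 and 2671 CPM in WT macrophage-like wells against 204 and 229 CPM in KO, and 90.6 and 80.0 against 142 and 104 CPM in fibroblast-like wells (difference of log2 differences −3.98, SE 0.387, edgeR adjusted p = 0.0133). For H2-Eb1 that difference was −3.62 (SE 0.426, edgeR adjusted p = 0.0297). Ly6a, a surface antigen of vessel and stromal cells, went the other way (2.82, SE 0.291, edgeR adjusted p = 0.0133). It was 105 and 151 CPM in WT macrophage-like wells against 485 and 516 CPM in KO, and 1510 and 1264 against 738 and 821 CPM in fibroblast-like wells. Endothelial markers rose in the same NCM macrophage-like wells, from 0.0370 and 0.0488% to 0.349 and 0.162% of other UMIs, so RNA of endothelial cells in these wells is not separated from a change of Ly6a in macrophages. For H2-Aa the classes lay closer together in KO, with endothelial-like wells at 341 and 228 CPM in WT against 202 and 159 CPM in KO. RNA shared by the wells of the KO chip is thus not separated from a change of class II genes in macrophages. H2-Aa, H2-Eb1 and Ly6a were all of the genes that passed among 15163, with 797 at an unadjusted p under 0.05. Between macrophage- and endothelial-like wells 12 genes passed, with 1224 at an unadjusted p under 0.05. The KO minus WT difference was higher in macrophage-like wells for 9 of them and lower for 3. Several of the 12, such as Cavin2, Cav1 and Fabp4, are made by endothelial cells. Between endothelial- and fibroblast-like wells edgeR called 0, with 711 at an unadjusted p under 0.05, and no other tool was run on this fit. Leaving out KO1 or KO2 gave 0 genes in the first 2 contrasts, and both fractions together, or only wells with at least 20000 UMIs and 1000 genes, gave 0 between macrophage- and fibroblast-like wells.

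**Figure D5:**
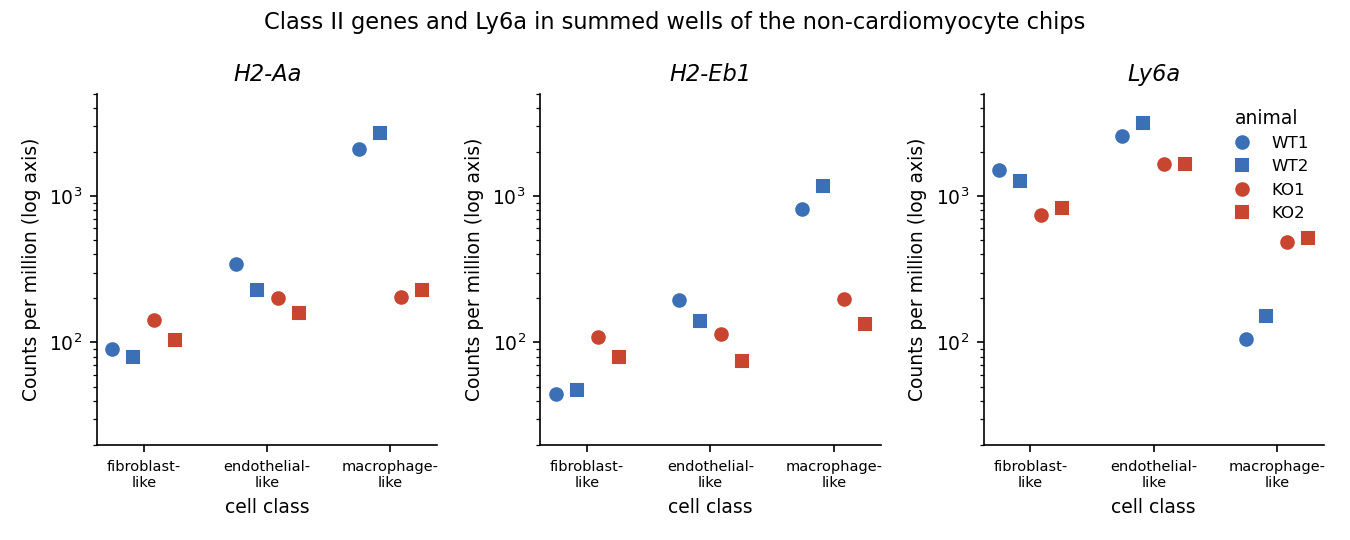
Expression in CPM (log axis) of H2-Aa, H2-Eb1 and Ly6a in fibroblast-, endothelial- and macrophage-like wells of the non-cardiomyocyte chips, 1 point per animal. In macrophage-like wells H2-Aa lay at 2107 and 2671 CPM in WT against 204 and 229 CPM in KO, and Ly6a at 105 and 151 against 485 and 516 CPM.

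At the preset correlation, camera called some of the fixed lists between classes, and none passed with an estimated correlation. Between macrophage- and fibroblast-like wells the class II list had a median difference of −2.39 (camera adjusted p = 4.31e-08; adjusted p = 0.231 with an estimated correlation), tissue-repair genes −1.46, inflammatory genes −0.98 and extracellular matrix genes 1.09, the last 3 each with adjusted p = 0.150 with an estimated correlation. For angiogenesis genes the KO minus WT difference was lower in endothelial-like than in fibroblast-like wells (median −1.42, camera adjusted p = 6.89e-07, adjusted p = 0.0731 with an estimated correlation). It was higher in macrophage-like than in endothelial-like wells (2.75, camera adjusted p = 7.98e-06, adjusted p = 0.110 with an estimated correlation). These are not levels within KO. Endothelial markers took 1.27 and 1.09% of other UMIs in KO endothelial-like NCM wells, against 0.349 and 0.162% in macrophage-like ones.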

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

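Of the tests in this part, the test of class II dilution was set before its result was seen, and the test between classes, the contaminant shares and the other tests of mitochondrial, haemoglobin, class II and atrial RNA were chosen afterwards. The genotype differences of H2-Aa, H2-Eb1 and Ly6a in macrophage-like wells of the NCM chips lay apart from those in fibroblast-like wells, by −3.98, −3.62 and 2.82 on the log2 scale (edgeR adjusted p = 0.0133, 0.0297 and 0.0133). Between macrophage- and endothelial-like wells 12 genes differed by the same test. Cavin2, Ly6a, Fabp4, Cav1, Depp1, Thrsp, Ecscr, Ms4a6d, Ptprr, Sptbn1, Ppbp and H2-Aa were these genes, and several of them are made by endothelial cells. Without KO1 or without KO2 both contrasts gave 0 genes, and with the stricter well filter the first gave 0. Outside the gene counts, read pairs removed as contaminant made up 3.51% of those of KO1's NCM wells, above the 0.614% of negative and the 0.988% of positive control wells, against 0.340% in KO1's CM wells. The NCM wells of WT1, WT2 and KO2 had 0.0274, 0.0145 and 0.0464%, so this share was high in 1 animal and not in the genotype.

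Mitochondrial and haemoglobin RNA were higher in KO wells of the NCM chips. Haemoglobin was also higher on the CM chips, at 0.00188 and 0.00220% of UMIs in WT against 0.1005 and 0.263% in KO. A difference of genotype in the mitochondrial RNA of the cells themselves, in both fractions, stays open. Among fibroblast-, endothelial- and macrophage-like wells, the difference on the CM chips was at most 0.208 of that on the NCM chips (6.06 points, SD 3.95, against 29.2 points, SD 9.35, in macrophage-like wells). Yet cardiomyocyte markers took 3.72 and 3.95% of other UMIs in the CM fibroblast-like wells of WT, against 0.0830 and 0.175% in the NCM ones. The mitochondrial share of such CM wells thus includes RNA of other cells, and the comparison does not decide. For the haemoglobin part, free RNA from broken red cells is a candidate source. The medians of haemoglobin UMIs per NCM well were compared over fibroblast-, endothelial-, macrophage- and neutrophil-like wells only. They lay within a ratio of 2.22 in a KO animal, at 306 to 374 UMIs in KO1 and 1593 to 3531 in KO2. In WT they were 20.5 to 39 in WT1 and 36.5 to 79 in WT2. Pericyte-like NCM wells, 9 in each KO animal, lay far higher, at 7623 in KO1 and 17569 in KO2. The RNA was thus not spread evenly over all classes. A difference between chips or days of preparation cannot be told apart from genotype, because there was 1 chip per genotype and fraction. A genotype effect limited to NCM cells was not tested.

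Class II RNA was lower in KO macrophage-like wells of the NCM chips. Whether dilution by RNA of other cells was the whole cause depended on the measure. The median log2 ratio of class II genes lay below that of macrophage markers in every pair of a KO and a WT animal. The gap was −0.886 in the pair nearest 0 and −1.47 in the farthest, which argues against dilution alone for the median gene. Summed shares of other UMIs, looked at afterwards, fell side by side. Class II genes went from 1.06 and 1.31% in WT to 0.555 and 0.592% in KO. Macrophage markers went from 2.57 and 2.85% to 1.46 and 1.36%, so dilution is not excluded for the summed set. The class II genes did not all fall alike. In CPM of the same UMIs, H2-Aa was 2341 and 2750 in WT against 282 and 249 in KO. H2-Eb1 was 898 and 1209 against 274 and 145. Both fell more than the sum, which thus does not describe them, but both were singled out by the test between classes. Whether there were fewer class II-high wells, with an unchanged level in the others, stays open. Wells were split at 30 H2-Aa UMIs, the gene in question, so a fall in every well would empty the upper part as well, and the ratio of at least 1.21 between WT and KO in the wells below decides nothing. A genotype difference that macrophage-like cells of both fractions share stays open too, because only 1 KO animal lay below both WT animals in class II percent on the CM chips (0.374 and 0.292% in WT against 0.601 and 0.179% in KO).

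Atrial RNA was higher in KO wells of the CM chips. Atrial RNA from broken cells, shared by the wells of a preparation, is a candidate explanation. The ratio of Myl7 to Myl2 was also higher in wells that are not muscle, by at least 2.79 times in each of 3 classes. Shared RNA of cardiomyocytes that make more Myl7 would raise this ratio too. The ratio thus does not tell atrial tissue from a change in the cardiomyocytes. In fibroblast-like wells the ratio was 0.0310 and 0.0109 in WT against 0.302 and 0.0905 in KO, and in macrophage-like wells 0.0555 and 0.0300 against 0.162 and 0.159. A fetal gene programme in ventricular cardiomyocytes stays open, because atrial genes exceeded fetal genes by log2 1.56, 0.853 and 0.577 in 3 pairs of animals but by −0.148 in the fourth. How much atrial tissue entered each preparation is not given in the sources used here, and a genotype effect on atrial genes was not separated from it.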

How the results depend on the processing

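Settings of a single fraction, of mitochondrial and haemoglobin genes left out together, and of clustering without them, and all settings of the test between classes, were chosen after the results were seen. Of 2542 alternatives for 131 results of named genes, 2289 stayed on the same side of the threshold in the same direction, 206 passed the threshold, 35 no longer passed it and 12 turned. For the lists called by animal, 502 of 633 alternatives kept the call and 33 turned the direction. All 633 used camera at the preset correlation. The estimated correlation and fry, under which nearly all calls were lost, are given below and were not among them. Of 201 alternatives for counts of changed genes, 161 stayed within 1.5 times. Only neutrophil-like wells by animal had a main count above 0, so in all other sums a count that stayed was 0 again. Likewise, named genes outside these wells had not passed at the start, so those that stayed had still not passed. Stk4 and Stk3 had 235 to 4500 UMIs per animal and fraction. Simulated changes lay only in genes with a mean of at least 10 CPM. At the same depth and a dispersion of 0.01, 100% of simulated 2-fold changes were recovered over all wells, 95.5% in neutrophil-like wells and 71.6% between macrophage- and fibroblast-like wells, against 4.48, 0 and 0% at the fitted dispersion. For such genes depth thus limits small folds in the last 2 tests, and the spread between animals limits all 3. Except where a setting holds fewer genes, wells or animals by its construction, the cause was not tested.

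Without the low-count filter, edgeR called 6 genes over all wells, 15 in fibroblast-like, 4 in endothelial-like and 56 in macrophage-like wells by library, and by animal 582 over all wells, 112 in cardiomyocyte-like, 293 in fibroblast-like, 101 in endothelial-like, 289 in macrophage-like and 106 in neutrophil-like wells. DESeq2's Wald test called 21, 23, 19 and 45 by library and 478, 110, 352, 109, 364 and 286 by animal in the same order. Thinning gave 2 genes in fibroblast-like and 10 in neutrophil-like wells, the NCM chips alone 13 in endothelial-like wells, and own marker scores 4 in macrophage-like wells. In neutrophil-like wells every non-control well gave 11 genes and Leiden resolution 2.0 gave 10, while clustering without mitochondrial and haemoglobin genes, or leaving these genes out, gave 0.

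Leaving out each library gave 0 to 48 genes in fibroblast-like wells, with 48 without WT replicate 2. Leaving out each animal gave 8 to 651 genes in cardiomyocyte-like wells (651 without KO2), 0 to 5 in endothelial-like, 0 to 3 in macrophage-like and 0 to 21 in neutrophil-like wells. The lone animal or library is then assumed to vary like the other genotype.

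Camera with an estimated correlation called 0 lists in every sum, and fry called 0 in every sum except 1 in macrophage-like wells by animal. In endothelial-like wells by library, camera called 5 lists, against 3 after thinning and 9 with a block on index order, and in macrophage-like wells by library 5 lists against 9 with that block. No count of changed genes moved with the block. Leaving out each library gave 9 to 15 lists over all wells, 9 to 14 in endothelial-like and 6 to 13 in macrophage-like wells. Leaving out each animal gave 4 to 14 lists in cardiomyocyte-like wells and 2 to 10 in neutrophil-like wells. By replicate number, no paired analysis was possible because the numbers follow accession order and libraries with the same number hold different fractions. The block on index order pairs libraries of the same fraction, and the labels pair no KO animal with a WT animal.

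For shares, the KO minus WT difference of endothelial-like NCM wells was 9.88 percentage points with the stricter well filter, 7.98 with every non-control well, 13.3 at Leiden resolution 0.5 and 12.8 with clustering without mitochondrial and haemoglobin genes, against −2.06. That of macrophage-like wells was −9.09, −10.7, −6.15 and −8.61 points with the stricter filter, Leiden resolution 0.5, own marker scores and clustering without those genes. That of cardiomyocyte-like CM wells was −15.3 points at Leiden resolution 2.0.

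Between classes, thinning gave 22 genes for endothelial- against fibroblast-like, 27 for macrophage- against fibroblast-like and 85 for macrophage- against endothelial-like wells. Both fractions together gave 0 and 3 in the last 2 contrasts, and every non-control well 5 and 23. Clustering without mitochondrial and haemoglobin genes gave 3 in the first contrast, the stricter filter 0 in the second, and Leiden resolution 0.5 and own marker scores 7 and 5 in the third. Leaving out each animal gave 0 to 10, 0 to 15 and 0 to 21 genes.

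Stk3 over all wells turned to 0.29 by library and 0.12 by animal in wells under 30% mitochondrial UMIs, to 0.15 by library after thinning and to 0.50 by animal on the CM chips, and leaving out 1 library or animal gave −0.33 to 0.23 and −0.59 to 0.12. In fibroblast-like wells thinning gave 0.10 for Stk4 and 0.11 for Stk3, and wells under 30% gave 0.18 for Stk3. In endothelial-like wells Stk4 was 0.12 at Leiden resolution 2.0 and 0.70 on the CM chips, and Stk3 was 0.042 after thinning. Leaving out each animal, Stk4 ranged from −0.32 to 1.25 in cardiomyocyte-like and from −2.31 to 0.56 in endothelial-like wells. Stk3 ranged from −0.21 to 0.67 in cardiomyocyte-like, −0.61 to 0.34 in fibroblast-like, −0.87 to 0.42 in endothelial-like and −0.12 to 1.31 in macrophage-like wells. On the CM chips alone H2-Ab1 (0.58) and Ackr4 (0.060) turned over all wells, mt-Tq (−0.12), mt-Nd2 (−0.016) and mt-Nd4 (−0.079) in endothelial-like wells, and Sptbn1 (−0.038), H2-Eb1 (0.47), H2-Ab1 (0.20), Il1a (0.30), Il1b (0.31), Alox5ap (0.089) and Fabp4 (−0.65) in macrophage-like wells.

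Settings that left under 20 wells in a sum were not run. By library this was wells under 30% mitochondrial UMIs in endothelial-like wells. By animal it was the same setting in every class except fibroblast-like wells, own marker scores and NCM chips alone in cardiomyocyte-like wells, CM chips alone in fibroblast-like wells, and Leiden resolution 0.5 and either fraction alone in neutrophil-like wells.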

Other observations

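The tests of pseudogene counts and of genes near the targets stand in this part, of which only the second was chosen after its result was seen. The receptor for leukotriene B4 that the series title concerns, encoded by Ltb4r1, was rare. It stood at 1.30 and 1.77 CPM in the NCM wells of WT1 and WT2 and at 0.792 and 0.745 CPM in those of KO1 and KO2, and in CM wells at 0.0956 and 0.0426 against 0.361 and 0.0870 CPM. In CPM of the UMIs that were neither mitochondrial nor haemoglobin, the NCM wells had 1.43 and 2.07 in WT against 2.12 and 1.44 in KO, which overlap. In macrophage-like wells the glycan sulphating enzyme Chst15 was 0.22 and 0.11 CPM in WT and 12.1 and 44.3 CPM in KO, and Sptbn1, a spectrin of the membrane skeleton, 89.2 and 77.8 against 301 and 437 CPM (edgeR adjusted p = 0.498 for both). In fibroblast-like wells Cd14, the co-receptor for endotoxin, was 31.2 and 31.1 against 152 and 131 CPM (log2 2.19, SE 0.283, edgeR adjusted p = 0.317). In endothelial-like wells Ptprr, a tyrosine phosphatase, was 82.3 and 111 against 5.25 and 10.8 CPM (log2 −3.58, SE 0.579, edgeR adjusted p = 0.863).

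Smaller classes of the NCM chips were too few to test. Lymphatic endothelial-like wells made up 2.85 ± 2.40% in WT and 0.484 ± 0.305% in KO (SD, n = 2 animals each; exact permutation p = 0.333). Per animal this was 1.16 and 4.55% against 0.699 and 0.268%. Pericyte-like wells made up 2.08% against 1.23%, endocardial-like wells 2.87% against 2.38% and T or NK cell-like wells 1.22% against 1.72%, as means over 2 animals. In the CM fraction fibroblast-like wells made up 9.40 ± 1.16% in WT and 4.85 ± 1.71% in KO (exact permutation p = 0.333). In cardiomyocyte-like wells the lipase inhibitor Angptl4 was 2.87 and 2.35 CPM in WT and 13.8 and 25.0 CPM in KO (log2 2.90), and the barrier protein gene Sprr2a1 0.22 and 1.99 against 32.0 and 36.3 CPM (log2 4.87), each at an edgeR adjusted p of 0.915.

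Fold changes of ribosomal protein pseudogenes lay near those of the parent genes. In macrophage-like wells the medians were log2 −0.431 and −0.409, a difference of −0.0222, and in cardiomyocyte-like wells the difference was the largest, at −0.132. Another rate of assignment in KO would need more than 0.5 in every class by the bound set before. Genes within 10 Mb of Stk4 or Stk3 did not stand out as a set, with 7.38% of 298 genes at an unadjusted p under 0.05 against 9.83% of 17593 elsewhere, a ratio of 0.751. A ratio of at least 1.5 was taken as the mark of donor strain variants after the result was seen. Single changed genes near the targets are not excluded by this share.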
